A study of Homo sapiens with 2 samples.

How the data were processed

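The deposited values come from universal protein binding microarrays, in which a tagged protein is applied to an array of double-stranded DNA and its amount on each spot is read by fluorescence. There are 2 samples, the ETS1 W356C full length protein and EGR1 DBD, 1 array each, and per the labels both were GST-tagged, expressed in E. coli and detected with an Alexa Fluor anti-GST antibody. Per the labels, the design holds 7 de Bruijn sequences, 3 of order 9, 2 of order 10 and 2 of order 11, in 2 chambers of 796 by 528 spots. Each file lists 412710 probes of 60 bases, of which 42 vary and the last 18, CAGAGCTGCGATGGTGCC, are shared; the other 7578 spots of the layout are not used here. The probes were assigned to the 7 sequences by the sequence name that each file lists for a probe, giving 9040 probes to each order-9 sequence, 37450 to each of order 10 and 155345 to each of order 11.

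The deposited values are a score per probe with mean 0 and SD 1 on each array, so the authors standardised them; the software and any background or spatial correction are not given in the sources used here. The design of the analysis had assumed an intensity. Because relative binding needs a true zero, the zero and the unit were recovered from the values. The most frequent value is shared by 1984 probes on the ETS1 array and 1027 on the EGR1 array, and relative to it, at 1 particular unit, 99.2% and 98.7% of sampled values are ratios of whole numbers, with median denominators of 1820 and 1335, against 1.00% and 0.625% at a shifted unit. That pattern is what a whole-number intensity divided by a local median leaves. The unit is 0.311 SD on the ETS1 array and 0.201 SD on the EGR1 array, with the zero at -0.422 and -0.480 SD. On the ETS1 array a unit of 0.155 or 0.104 SD fits as many values. The unit of 0.311 SD was kept by rule, as the largest unit within 1 percentage point of the highest share of such ratios. Of its denominators 74.3% are odd, 33.1% of those have an odd numerator and 24.6% of denominators divide by 3. The shares are close to those on the EGR1 array (75.0%, 33.3% and 24.7%), while each smaller unit departs from this in at least 1 share. They did not enter the choice of the unit. A smaller unit would make ETS1 folds larger. Signal therefore means intensity in units of the local median; the array median is 1, no probe is at or under 0, and background that was not subtracted remains in it, so folds near background are understated.

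A k-mer was counted on a probe if it or its reverse complement lies in the variable bases. Relative binding is the log2 of the median signal of the probes holding the k-mer over the median of all probes. Intervals are 95% percentile intervals from 1000 bootstrap resamples of probes, with 3 exceptions. Means over weaker sites also resample the sites, the ceiling test resamples pairs, and comparisons of sets of 8-mers resample 8-mers. The enrichment score is the area under the ROC curve minus 0.5 for probes holding an 8-mer against all others, with thresholds of 0.45 and 0.35. Double substitutions were called when the interval of the observed change minus the sum of the single changes excluded 0. Paired cores were taken from probes with exactly 2 GGAA on either strand, by orientation and spacings of 0 to 15 bp. Head to head means GGAA followed by TTCC as listed, tail to tail the opposite order. Held-out prediction used 5 random folds, k of 6 to 11 and at least 3 training probes per k-mer. Levels of different probes were set against each other within an array, as is usual for this assay, in which 1 labelled protein is read on all spots. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with seed 7.

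The steps were tested on simulated data on the same probe sequences. Of 200 8-mers given known folds over log2 noise of SD 0.5, with 50 at each size, median recovered folds were 1.93 for 2, 3.77 for 4, 7.37 for 8 and 14.5 for 16. All 50 of the 16-fold 8-mers, none of the smaller ones and 0 of the other 8-mers tested reached a score of 0.45. These scores set no limit for the real arrays, since a score depends on how many other probes are bright. On the ETS1 array CCGGATAT, with a median signal of 4.82, scored 0.459. For additive sites with log2 noise of SD 1, 0 of 25 testable ETS1 pairs and 7 of 240 testable EGR1 pairs were called, all 7 above the sum.

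The sequences named were fixed by rule before the data were examined: 4 lists of sites (ETS family, EGR family, GC box and KLF, other families), the 10 8-mers of highest score and the 5 10-mers of highest signal with at least 10 probes per array, the 5 most and 5 least harmful single substitutions, the 3 highest and 3 lowest flanks, and the 5 largest deviations of double substitutions each way with an expected level above the array median. Of the other families, named sites are those with the highest values. Alternatives were the mean of log2 signals, leaving out the 1% brightest and dimmest probes, leaving out each de Bruijn sequence, leaving out probes with another core, leaving out sites within 3 bases of the free end, other score thresholds, 5-base cores and other prediction scores. Chosen after seeing the data were a zero at the dimmest probe and leaving out sites in the starts nearest the shared end. The files used here list no spot rows, columns or flags, so no spatial correction was tried.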

Results

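The data were 2 protein binding microarrays, 1 per protein, that each measured how much of a purified human transcription factor was held by 412710 different double-stranded DNA probes. One array carried the ETS1 W356C full length protein in chamber 1, and the other carried EGR1 DBD, the DNA-binding domain, in chamber 2. ETS1 below means this W356C form, and no ETS1 without that change was measured. ETS1 is a member of the ETS family, which recognises a GGAA core through a winged helix domain, and EGR1 is a zinc finger protein that recognises G-rich sites. Both proteins were made in E. coli with a GST tag and read with a fluorescent antibody against that tag. With 1 array per protein there were no replicate arrays, so no difference between the proteins was tested and no p-value is given. Errors are 95% bootstrap intervals over the probes that hold a sequence, or the SD over the 7 de Bruijn sequences of the design where stated. For means over weaker sites the sites were resampled too. All these errors cover the spread between spots of 1 hybridisation. Protein, construct and chamber changed together and cannot be told apart. Signal is given in units of the array median, so a typical probe has a signal of 1, and relative binding is the log2 of that value.

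In units of the array median, signal on the ETS1 array was concentrated on few probes, and signal on the EGR1 array was spread over more. On the ETS1 array the quartiles lay at 0.951 and 1.07, 4.59% of probes exceeded 2 and 0.871% exceeded 10, with a highest value of 298. On the EGR1 array the quartiles lay at 0.639 and 1.95, 24.4% of probes exceeded 2 and 4.35% exceeded 10, with a highest value of 389. The 99th percentile was 8.79 on the ETS1 array and 25.9 on the EGR1 array. The dimmest probe lay at 0.694 on the ETS1 array and 0.192 on the EGR1 array, so background left in the median can differ between them. These shares and percentiles therefore do not compare the amounts bound by the proteins.

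Every 9-mer was covered many times. Counting both strands, a 9-mer was held by a mean of 106.9 probes, with a range of 77 to 129. Each of the 3 order-9 sequences alone held a 9-mer on a mean of 2.34 probes, and the other 6 sequences together held it on 104.6, close to the 2 and 105 that the design text gives. When only the strand as listed was counted, the mean over all probes was 53.5.

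The 8-mers with the strongest enrichment belonged to the recognised motif of each protein, and no 8-mer passed the threshold on both arrays. Of 32896 8-mers, 12 reached an enrichment score of 0.45 on the ETS1 array and 41 on the EGR1 array. Of the 12 ETS1 8-mers, 9 (75%) held GGAA, against 3.89% of all 8-mers, and the other 3, CCGGATGT, ACCGGATG and CCGGATAT, held GGAT. Of the 41 EGR1 8-mers, 36 (87.8%) held a run of 6 bases from GCGTGGGCG or GCGGGGGCG, against 1.02% of all 8-mers. The 5 EGR1 8-mers outside this definition, named after their values were seen, were GTGGGTGG, TGTGGGGG, GTGGGTGT, GGGGGTGG and TGGGGGTG, with median signals from 12.5 to 20.9.

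CCGGAAGT ranked highest on the ETS1 array, with an enrichment score of 0.481 and a median signal of 14.7 (12.6 to 17.5) over 451 probes. It was followed by ACCGGAAG (11.2), CCGGAAAT (9.89), CCGGATGT (8.51), CCGGAAGC (6.64), CCGGAAAC (5.80), ACCGGAAA (7.37), ACCGGATG (5.92), CCGGATAT (4.82) and GCCGGAAG (5.14), in the order of their scores and with median signals in parentheses. On the EGR1 array TGCGTGGG ranked highest, with a score of 0.488 and a median signal of 33.7 (31.6 to 35.3) over 439 probes. CGTGGGCG had the highest median of the leading 10, 36.2, and GTGGGCGG (28.9), TGGGGGCG (20.6), CGGGGGCG (23.3), GCGGGGGC (21.2), GCGTGGGC (32.7), CGCGTGGG (24.4), GTGGGCGT (31.5) and GGGGGCGT (22.2) made up the rest. The numbers of 8-mers depended on the threshold: at 0.40 there were 54 on the ETS1 array and 132 on the EGR1 array, at 0.48 there were 1 and 3, and a score over the brighter part of the probes passed 108 on each array.

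Each protein bound its consensus strongly and left the other consensus near background. ACCGGAAGT had a median signal of 33.9 (28.1 to 38.2) over 103 probes on the ETS1 array, a relative binding of 5.08, and 0.967 (0.843 to 1.16) on the EGR1 array. GCGTGGGCG had a median signal of 47.3 (43.9 to 53.9) over 110 probes on the EGR1 array, a relative binding of 5.56, and 1.05 (1.03 to 1.08) on the ETS1 array. All 103 ACCGGAAGT probes on the ETS1 array and all 110 GCGTGGGCG probes on the EGR1 array exceeded a signal of 2. Computed within each de Bruijn sequence, relative binding was 5.30 ± 0.52 (SD, n = 7 sequences) for ACCGGAAGT and 5.73 ± 0.33 (SD, n = 7 sequences) for GCGTGGGCG. The ETS1 value rests on where the zero of the scale lies: with the zero at the dimmest probe, an alternative chosen after seeing the data, it was 6.76. Leaving out the 1% brightest and 1% dimmest probes, which removes most probes of each consensus, gave 2.46 for ETS1 and 4.28 for EGR1.

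The 10-mers with the highest signals, among those with at least 10 probes, held the consensus or differed from it at 1 base. On the ETS1 array these were AACCGGAAGT with a median of 42.4 (19.6 to 60.3), ACCGGAAATG with 40.9, ACCGGAAGTT with 37.8, CACCGGAAGT with 35.7 and ACCGGAAGTC with 35.1. On the EGR1 array they were GCGTGGGCGT with 55.9 (45.0 to 68.5), TGCGTGGGCG with 54.1, TACGTGGGCG with 53.7, CGCGTGGGCG with 50.7 and GCGTGGGCGG with 50.2. Each rests on 22 to 30 probes, and the intervals of the 5 overlap on both arrays.

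The single substitution scan asked which bases of each site carry the binding, with positions counted from 1 at the first base of the site as printed. In ACCGGAAGT the GG of the core could not be replaced: each of the 6 substitutions at positions 4 and 5 fell to the array median, a loss of 33.4-fold to 34.3-fold. The 5 with the lowest signals were G4C (34.3-fold, 28.4 to 38.6), G4T, G5T, G5A and G4A, all at the array median, so their order carries no information. The least harmful were G8A (1.21-fold, 0.910 to 1.59), A1G (1.94-fold), A7T (2.05-fold), T9C (2.13-fold) and C2G (3.21-fold), so that the GGAT site ACCGGATGT kept a relative binding of 4.05. By position, the mean loss was 2.88-fold at position 1, 12.7-fold at position 3, 29.4-fold at position 6 and 3.90-fold at position 9. Of the 27 substitutions, 26 had an interval of the change below 0, G8A being the exception, and 15 lost over 10-fold. Losses at positions 4 and 5 are lower bounds, since the substituted sites are at background.

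GCGTGGGCG tolerated changes at both ends but not at positions 3, 6 and 7. The mean change in relative binding was -4.26 at position 3, -4.64 at position 6 and -3.96 at position 7. At positions 4 and 5 it was -1.64 and -1.97, and at positions 1, 2, 8 and 9 it was -0.54, -0.88, -0.77 and -0.79. The most harmful substitutions were G6T (31.4-fold, 23.1 to 41.4), G7C (28.1-fold), G6A (27.1-fold), G3T (a change of -4.76) and G3C (21.5-fold). The least harmful were C8T (1.17-fold, 1.05 to 1.35), G1A (1.29-fold), C2T (1.44-fold), T4G (1.47-fold) and G1C (1.51-fold). All 27 intervals lay below 0, 9 substitutions lost over 10-fold and 11 lost less than 2-fold. With the 1% brightest and 1% dimmest probes left out, intervals below 0 numbered 16 for EGR1 and 17 for ETS1, and the changes of G1A and C2T turned to 0.14 (-0.31 to 0.40) and 0.032 (-0.27 to 0.36).

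**Figure D1:**
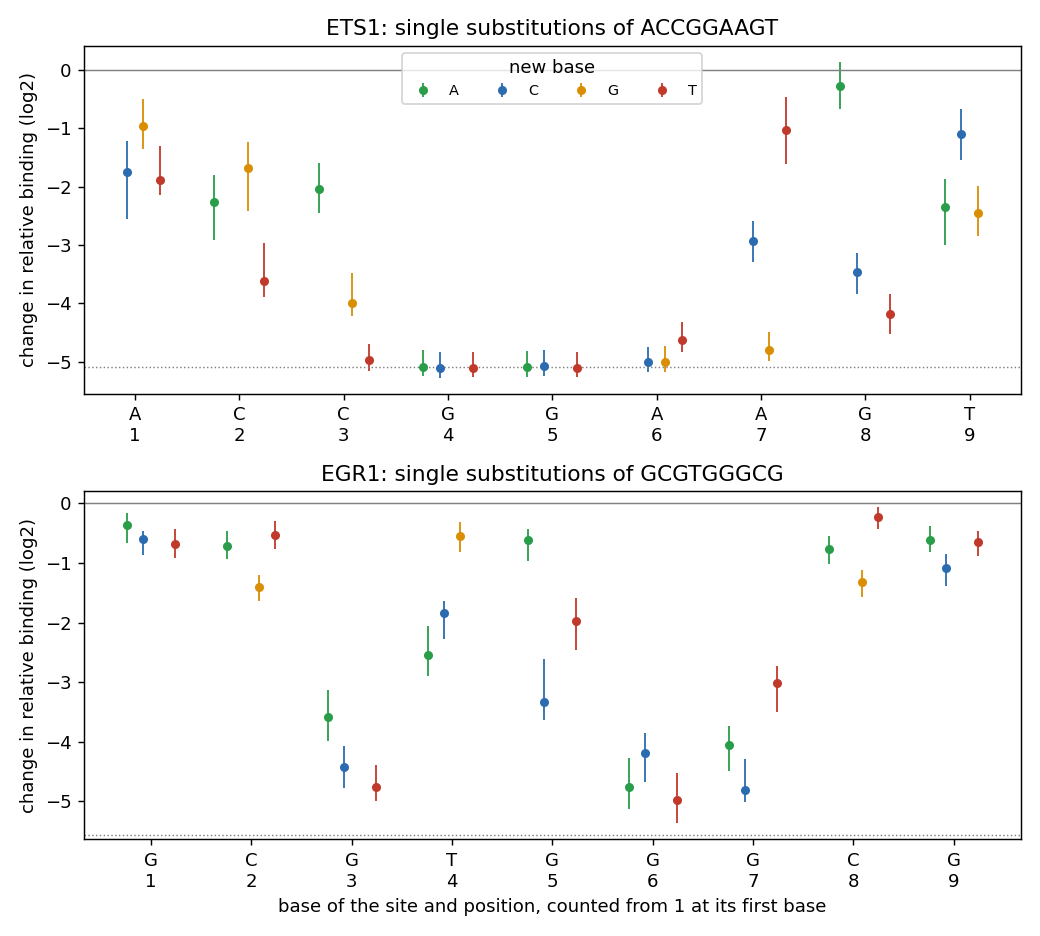
Change in relative binding (log2, vertical axis) for each single substitution of ACCGGAAGT on the ETS1 array and GCGTGGGCG on the EGR1 array, by position of the site, with 95% bootstrap intervals over probes as bars and the new base as colour. The dotted line marks the array median, which substitutions at positions 4 and 5 of the ETS1 site reach, while positions 3, 6 and 7 of the EGR1 site lose most.

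The flank comparison asked how far bases next to the site matter, since the series concerns long sites. For ETS1 the base before CCGGAAGT mattered and the base after it had little effect. Averaged over the bases on the other side, signal was 32.5 with A before the site, 17.7 with G, 11.1 with C and 9.29 with T, a range of 3.50-fold, whereas the base after the site gave 14.4 to 17.3. ACCGGAAGTT (37.8), ACCGGAAGTC (35.1) and ACCGGAAGTA (32.9) were highest of the 16 flanked sites, and TCCGGAAGTC (8.93), TCCGGAAGTT (8.18) and CCCGGAAGTT (6.91) were lowest. The highest exceeded the lowest by 5.47-fold, a log2 difference of 2.45 (1.21 to 3.58). With the 1% brightest and 1% dimmest probes left out, this difference was 0.10.

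The 16 flanked sites had a smaller range for EGR1, but unlike positions are compared. The base before CCGGAAGT is position 1 of ACCGGAAGT, already covered by the substitution scan, whereas both EGR1 flanks lie outside GCGTGGGCG. The base after CCGGAAGT, the only ETS1 flank outside ACCGGAAGT, changed the mean by a smaller fold (14.4 to 17.3) than either EGR1 flank. TGCGTGGGCGT (64.7), TGCGTGGGCGA (59.8) and TGCGTGGGCGG (55.5) were highest, CGCGTGGGCGA (41.7), AGCGTGGGCGC (36.3) and GGCGTGGGCGC (34.0) were lowest, and the base before the site changed the mean by 1.34-fold and the base after it by 1.31-fold. The highest exceeded the lowest by 1.90-fold, a log2 difference of 0.93 (0.11 to 1.77), over 4 to 12 probes per site. Because the extremes were picked from 16 sites, both differences overstate what a flank chosen in advance would give.

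Double substitutions asked whether losses add on the log2 scale. For ETS1 most pairs that could be tested lay within error of the sum. Of the 252 double substitutions of CCGGAAGT, 23 had an expected level above the array median, and 2 of these deviated, TCGGATGT (C1T with A6T, 0.39 above the sum) and CGGGAAAT (C2G with G7A, 0.30 above), positions counted from 1 at the first base of CCGGAAGT. None deviated downward, and of the 9 with an expected level over 2 times the median none deviated at all. Over all 252 pairs, 231 lay above the sum, since signal cannot fall below background. The 2 deviating pairs depend on the setting. Pairs with an expected level above the array median were picked anew in each setting, so the following counts are not shares of the 23. When log2 signals were averaged 16 lay above the sum, and 0 did without probes holding another GGAA. Without sites in the starts nearest the shared end, an alternative chosen after seeing the data, 7 lay above it.

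For EGR1 many pairs departed from the sum on the log2 scale. Of 242 double substitutions of GCGTGGGCG with an expected level above the array median, 95 (39.3%) lay below the sum of the single changes and 28 (11.6%) above it. Substitutions at neighbouring positions went the other way, with 15 of 46 pairs above and 8 below, while 13 of 196 pairs apart lay above and 87 below. The largest shortfalls were TCGTTGGCG (G1T with G5T), with a relative binding of 0.59 against an expected 2.92, a deviation of -2.33 (-2.87 to -1.72), then CCGTTGGCG (-2.08) and GTGTTGGCG (-2.03). GAGTTGGCG, with a signal of 1.84 against an expected 7.36, and GCGCGGGCT, with 2.11 against 8.43, complete the 5, of which 4 carry G5T. The largest excess was GCATGGGGG (G3A with C8G), with a signal of 10.3 against an expected 1.58, a deviation of 2.71 (2.13 to 3.17), then GCGTGGAGG (1.83), GCGCGGGGG (1.59), GCGTGCGGG (a signal of 2.92 against 1.03) and GCTGGGGCG (1.46), of which 4 carry C8G. The balance depends on the scale of addition: with changes added on a bound-over-unbound scale, 30 pairs lay above and 88 below for the best-fitting ceiling, 10 times the consensus signal (mean square deviation 0.694). Ceilings from 1.1 to 10 times were tried, so this is the edge of the range, and no ceiling gave 0.694 as well. With poorer fits, 40 lay above and 72 below at 3 times (0.705), 52 above and 57 below at 2 times (0.752), and 82 above and 21 below at 1.5 times (0.940). In additive sites simulated on the same probes, 7 of 240 pairs lay above and 0 below. Without the 1% brightest and 1% dimmest probes, 16 of 274 pairs (5.84%) lay above the sum and 47.8% below it. That setting also shifted the expected levels of the 242 pairs, up for 164 and down for 78.

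**Figure D2:**
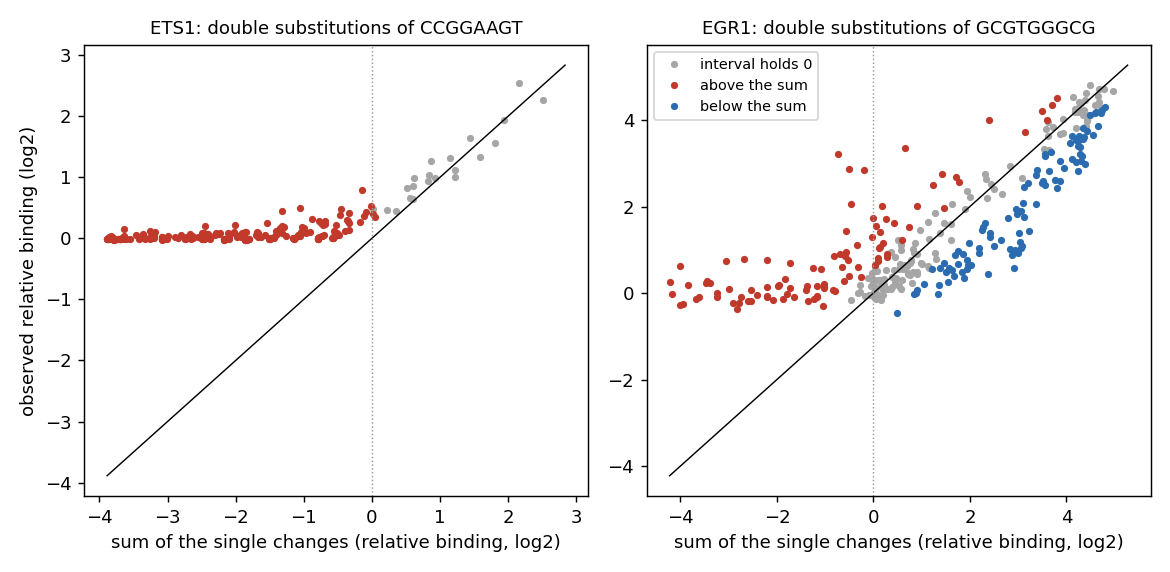
Observed relative binding (log2, vertical axis) of every double substitution of CCGGAAGT on the ETS1 array and GCGTGGGCG on the EGR1 array against the level expected from the sum of the single changes (log2, horizontal axis), each point 1 sequence, coloured by whether its 95% bootstrap interval lies above, below or across the sum. Right of the dotted line at the array median, 95 EGR1 points lie below the sum and 28 above, against 0 and 2 for ETS1.

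The design text sets 1 order-9 sequence, with few probes per 9-mer, against the rest of the design. The few probes ranked the consensus near the top but gave a noisy picture of other 9-mers. The labels do not say which order-9 sequence was meant, so each was taken in turn. Across 131072 9-mers, which are not independent replicates, the median signal in the single sequence and in the rest correlated with Pearson r of 0.303, 0.319 and 0.321 on the ETS1 array (Spearman rho 0.174, 0.171 and 0.186) and 0.394, 0.375 and 0.380 on the EGR1 array (0.236, 0.219 and 0.243). In the rest, ACCGGAAGT on the ETS1 array and GCGTGGGCG on the EGR1 array ranked 1 in all 3 cases. In the single sequences, where each rests on 2 probes, ACCGGAAGT ranked 1, 208 and 1, and GCGTGGGCG ranked 27, 57 and 1. Of the leading 100 9-mers, 7 to 13 were shared on the ETS1 array and 17 to 35 on the EGR1 array.

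Held-out prediction asked which k-mer length best predicts probe signal, and in the main score 9 bases did so for both proteins. When a held-out probe was predicted by its best k-mer, Pearson r rose from 0.484 at 6 bases to 0.638 at 8 and 0.663 at 9 for ETS1, then fell to 0.651 at 10 and 0.473 at 11. For EGR1 it rose from 0.645 at 6 bases to 0.725 at 8 and 0.737 at 9, then fell to 0.728 at 10 and 0.603 at 11. The SD over the 5 folds was 0.002 to 0.008. The length with the highest r depended on the score, since summing linear k-mer values instead of taking the best gave the highest r at 8 bases, 0.672 for ETS1 and 0.732 for EGR1. Longer k-mers also rest on fewer probes, so the peak does not measure site length alone. Between random parts of the probes, k-mer values at 8, 9 and 10 bases correlated with r of 0.931, 0.809 and 0.550 for ETS1. For EGR1 these were 0.949, 0.849 and 0.609.

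**Figure D3:**
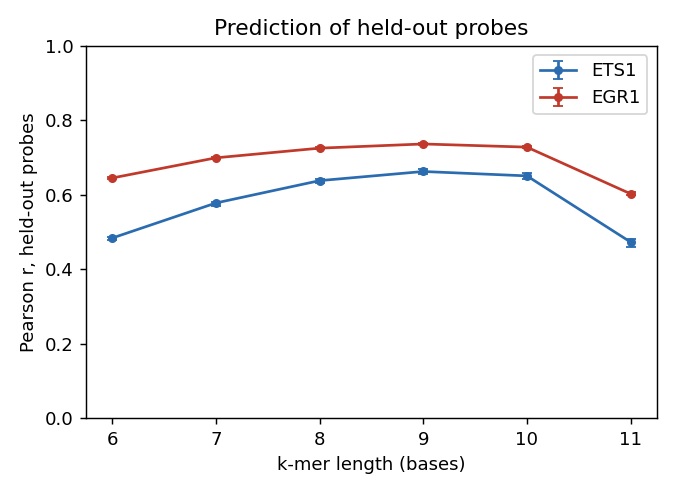
Pearson r between predicted and measured log2 signal of held-out probes (vertical axis, no unit) by k-mer length in bases (horizontal axis) for the 2 arrays, with bars from the lowest to the highest of 5 folds. Both curves peak at 9 bases, at 0.663 for ETS1 and 0.737 for EGR1, and fall at 11.

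Paired GGAA cores were examined because full-length ETS1 is known to bind some paired sites, though the protein here was the W356C form. One arrangement stood out: probes with 2 cores tail to tail at spacing 0, which is TTCCGGAA, had a median signal of 3.30 over 189 probes, a log2 excess of 1.55 (1.21 to 1.83) over pairs of the same orientation more than 15 bp apart. At spacing 1, head to head and tail to tail pairs both had a median of 1.31, with excesses of 0.34 (0.21 to 0.50) and 0.22 (0.08 to 0.41). Probes with exactly 1 core had a median of 1.03. Of the 16 spacings in each orientation, 11 lay above distant pairs head to head, 6 in tandem and 2 tail to tail, where 1 lay below, but apart from those named the excess was at most 0.16. The distant pairs themselves had medians of 1.04 head to head, 1.08 in tandem and 1.12 tail to tail. These counts therefore do not rank the orientations, since each was set against a different level. A spacing of 0 or 1 also fixes the bases next to each core, so the pair and the flank cannot be told apart here. The count of 19 is fragile, since it was 12 when log2 signals were averaged, 3 for GGAAG cores, 2 for CGGAA cores and 10 to 19 when 1 de Bruijn sequence was left out.

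Where the site lay on the probe mattered for ETS1, and for EGR1 it made little difference at the consensus but some at weaker sites. Starts are counted from 1 at the end of the 42 variable bases that lies away from the shared 18 bases. Probes with exactly 1 CCGGAAGT had a median signal of 35.7 for starts 1 to 12 (153 probes), 17.9 for starts 13 to 24 and 4.71 for starts 25 to 35 (146 probes), a 7.57-fold fall and a log2 difference of 2.92 (2.58 to 3.36). Probes that carry the site as written had a median of 10.0 and those with its reverse complement 28.0, a log2 difference of -1.48 (-1.95 to -0.99). GCGTGGGCG on the EGR1 array had medians of 43.1, 55.0 and 46.3 in the 3 ranges, with a difference of -0.10 (-0.34 to 0.07) between starts 1 to 12 and 24 to 34, and of -0.27 (-0.53 to 0.02) between strands, which was -0.40 (-0.69 to -0.14) when log2 signals were averaged. Of 8 singly substituted EGR1 sites with signals of 3 to 20, 7 fell toward the shared end, with a mean log2 difference of 0.57 (0.08 to 1.07), and GCGCGGGCG (1.32, 0.37 to 1.95), GCATGGGCG (1.08, 0.46 to 1.98) and GCGTGGGGG (0.71, 0.26 to 1.23), named after their values were seen, had intervals above 0. The ETS1 minus EGR1 difference at the 2 sites was 3.02 (2.66 to 3.51) for position and -1.21 (-1.79 to -0.75) for strand, with intervals that hold the spread between probes and none between arrays. With the 1% brightest and 1% dimmest probes left out, which drops 292 of the 451 CCGGAAGT probes, the ETS1 position difference turned to -0.25 (-1.52 to 0.62).

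**Figure D4:**
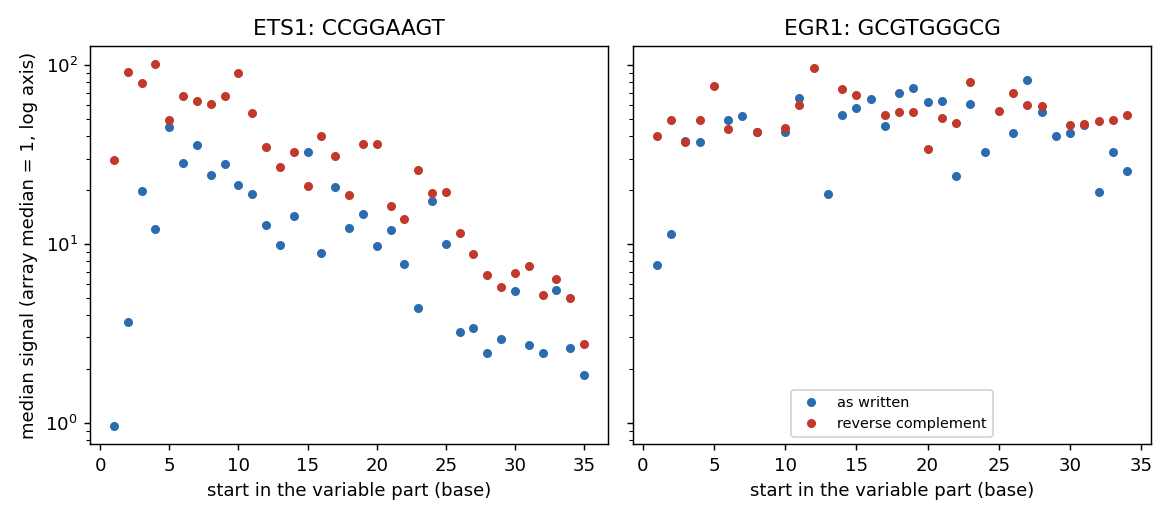
Median signal (vertical axis, log scale, array median = 1) of probes with exactly 1 copy of CCGGAAGT on the ETS1 array or GCGTGGGCG on the EGR1 array, by start in the variable part (bases, horizontal axis) and strand as colour, each point 1 start and strand. ETS1 range medians are 35.7, 17.9 and 4.71 from the free end toward the shared end, with low points at starts 1 and 2 of the strand as written (0.957 and 3.65), and EGR1 range medians are 43.1, 55.0 and 46.3.

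The fixed site lists separated the proteins. All 10 ETS family sites reached an enrichment score of 0.35 on the ETS1 array and 5 of them 0.45, with median signals from 1.74 for TCGGAAGT and 1.77 for GAGGAAGT to 33.9 for ACCGGAAGT, while on the EGR1 array none reached 0.35. All 10 EGR family sites reached 0.45 on the EGR1 array, with median signals from 27.8 for GCGTGGGAG to 47.3, and GCGTGGGTG (40.3), ACGTGGGCG (36.7) and GCGGGGGCG (32.2) next to the consensus. Of the 4 GC box and KLF sites, which other zinc finger proteins recognise, 3 reached 0.35 on the EGR1 array and none reached 0.45: GGGGCGGGG had a signal of 10.5, CCCCGCCC 8.78, GGGGTGGGG 7.32 and CCACACCC 2.80. On the ETS1 array the EGR family sites had scores from 0.105 to 0.226 and signals from 1.02 to 1.13. Of the 15 sites of other families, 1 reached 0.35 and on the ETS1 array only: the STAT site TTCCCGGAA, which contains GGAA, with a score of 0.367 and a signal of 1.73. On the EGR1 array the highest of these 15 was the E-box CACGTG, with a signal of 1.46 (1.41 to 1.52).

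The arrays shared few bright probes. Across the 412710 probes, which are not independent replicates, Pearson r was 0.016 on the linear scale and 0.123 on the log2 scale, and Spearman rho was 0.297. Of the brightest 1%, 4128 probes on each array, 40 were shared, against 41.3 expected by chance. Across the 32896 8-mers Pearson r of the relative binding was 0.134 and Spearman rho 0.523. As a check on noise, the probes of 1 array were split at random into equal parts. The 8-mer values of these parts correlated with Pearson r of 0.931 for ETS1 and 0.949 for EGR1, and Spearman rho of 0.449 and 0.710. The parts share no probes, whereas an 8-mer lies on the same probe sequences on both arrays. The correlations within an array therefore set no limit for those between arrays. What the shared probe sequences add to the correlation between arrays was not tested.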

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

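The test of whether a ceiling accounts for the whole difference was chosen only after the result was seen, and the others were fixed before their results. With 1 array per protein, the intervals hold the spread between probes or sites and none between arrays, so a difference between the proteins was not tested. The effect of position differed between these 2 arrays by 3.02 (log2, 2.66 to 3.51): the signal of CCGGAAGT fell by 2.92 from starts 1 to 12 to starts 25 to 35 on the ETS1 array, and the same difference, early minus late starts, was -0.10 for GCGTGGGCG on the EGR1 array. Strand also differed between the arrays, by -1.21 (-1.79 to -0.75), with -1.48 on the ETS1 array and -0.27 on the EGR1 array. The tables argue against uneven flanks, since within 8 classes of strand and base before the site the ETS1 fall was still 2.76 (2.34 to 2.92), and against site strength, since 6 weaker ETS1 sites with signals of 3 to 20 fell by 2.88 (2.57 to 3.16) on average. A ceiling of the EGR1 signal may hide part of a fall, as 8 weaker EGR1 sites fell by 0.57 (0.08 to 1.07), but the gap between the weaker sites of the arrays stayed at 2.31 (1.72 to 2.88), so a ceiling is not the whole difference between these 2 arrays. The full-length ETS1 W356C protein and the chamber remain open and untested, because construct and chamber changed together.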

How the results depend on the processing

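Zero at the dimmest probe and leaving out sites in the starts nearest the shared end were chosen after seeing the data, the other alternatives before. No paired analysis was possible because each group has 1 array. Spatial correction and spot flags were not run, and a filter on signals at or under 0 removes nothing. When each de Bruijn sequence was left out in turn, relative binding of the consensus ranged from 5.07 to 5.13 for ETS1 and 5.54 to 5.59 for EGR1, and 204 main values were classed as unchanged while 6 moved. A count was classed as unchanged within a ratio of 1.5 to the main count, and any other value within its interval or spread. The exceptions were ETS1 pairs above the sum (0 to 3) and paired-core spacings above distant pairs (10 to 19). Of 702 single substitution changes under alternatives, 699 stayed below 0.

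Without the 1% brightest and 1% dimmest probes, relative binding fell to 2.46 (ETS1) and 4.28 (EGR1), substitutions with an interval below 0 to 17 and 16, the ETS1 flank difference to 0.10 and the median of the ETS and EGR family sites to 1.53 and 4.13. Of the 51 ETS1 pairs testable at this setting, 1 lay above and 3 below the sum. EGR1 pairs were 16 above, with 47.8% of 274 below. Position differences were -0.25 (ETS1) and -0.57 (EGR1), the ETS1 strand difference was -0.75, and the changes of G1A and C2T in the EGR1 site were 0.14 and 0.032. This setting removes 92 of 103 ACCGGAAGT probes and 96 of 110 GCGTGGGCG probes by construction, and no EGR1 flank difference could be had.

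With log2 signals averaged, relative binding was 4.71 and 5.17, the ETS1 position difference 2.56, the EGR1 strand difference -0.40 (-0.69 to -0.14), ETS1 pairs above the sum 16, spacings above distant pairs 12, and the median of the EGR family and the GC box and KLF sites 4.46 and 2.71. The correlations of 9-mers between an order-9 sequence and the rest were 0.364, 0.387 and 0.387 (ETS1) and 0.461, 0.442 and 0.443 (EGR1).

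With the zero at the dimmest probe, relative binding was 6.76 and 5.86, medians of the ETS family, EGR family and GC box and KLF sites 3.87, 5.26 and 3.27, and ETS1 pairs above the sum 6. Without sites in the starts nearest the shared end, ETS1 relative binding was 5.32 and ETS1 pairs above the sum 7. Those pairs were 0 without probes with another core and 1 without sites near the free end.

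At score thresholds of 0.40 and 0.48, 8-mers numbered 54 and 1 (ETS1) and 132 and 3 (EGR1), and 108 on each array over the brighter part of the probes. Spacings above distant pairs were 3 for GGAAG and 2 for CGGAA. The probe correlation between arrays was 0.123 on the log2 scale and 0.077 without the 1% brightest probes, where the 8-mer correlation was 0.188. On the listed strand, 9-mers had 53.5 probes. Summing linear k-mer values gave r of 0.590, 0.650, 0.672, 0.647, 0.560 and 0.401 (ETS1, k of 6 to 11) and 0.683, 0.718, 0.732, 0.726, 0.683 and 0.548 (EGR1). At least 10 training probes gave 0.161 and 0.247 at k of 11, where few probes could be predicted. The causes of these shifts were not tested except where stated. Signal over background limits what can be said of strong losses, since ETS1 sites with a substitution at position 4 or 5 lie at the array median.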

Other observations

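In this part, the tests of other sites on the probe, of runs of G and of the order of EGR1 8-mers were chosen only after the result was seen, as was the interval of the ceiling test below. Median signals were higher for 8-mers of G and C only, 1.02 on the ETS1 array and 1.72 on the EGR1 array, than for those without G or C, 0.995 and 0.940. On the EGR1 array 8-mers with 4 G or C were still at 0.942.

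Several of the brightest spots held no recognised core. Of the 10 brightest probes, 4 on the ETS1 array held GGAA and 2 on the EGR1 array held a 6-base EGR1 run, against 26.9% and 10.9% of all probes, while among the brightest 100 these numbers were 78 and 88.

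The EGR1 double substitutions lay below the sum of the single changes in 95 pairs and above it in 28. Without probes holding another run of bases from GCGTGGGCG or GCGGGGGCG, pairs below still outnumbered pairs above by 3.38 times. Probes with such a second run are therefore not needed for the excess. The filter leaves other EGR1 sites in place, since 141 of the 318 EGR1 8-mers with a score of at least 0.35 hold no such run. It therefore cannot decide whether other EGR1 sites in general contribute. Changes were also added on a bound-over-unbound scale, with ceilings from 1.1 to 10 times the consensus signal. The best-fitting of these was the largest tried, 10 times, and it left 2.93 times as many below as above. That point value alone passes the limit of 2 set beforehand for ruling a ceiling out, but its interval, 1.82 to 3.96, does not. This interval resamples the 242 pairs, which share the consensus and 27 single substitutions, so error common to many pairs is left out. The mean square deviation was 0.694 with that ceiling or with none. A ceiling therefore stays open, and one at 2 times the consensus balanced the calls at 52 above and 57 below with a mean square deviation of 0.752.

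The 8-mers ranked alike on the arrays, with a Spearman rho of 0.523, although the proteins share no strong 8-mer. G and C content alone does not account for this, since rho within classes of equal content was 0.473. Runs of G may contribute, as all 98 core-free 8-mers with at least 5 G in a row were higher on the ETS1 array by a median of 0.087 (log2, 0.084 to 0.091) than others of the same base counts. These 8-mers were also bright on the EGR1 array, with relative binding from 1.51 to 3.47. A trace of EGR1 in the ETS1 chamber could therefore raise them too, and this test cannot tell such a trace from runs of G. Such a trace could add to the shared ranking, since 37 of the 38 testable high EGR1 8-mers were higher on the ETS1 array than others of the same base counts, by a median of 0.058 (0.046 to 0.076). Among these 38 the signals on the arrays ranked in opposite order, with a rho of -0.484 (-0.673 to -0.188), so a trace alone does not set their order. That interval resamples the 38 8-mers, many of which overlap in sequence. The order of the other 8-mers was not tested in this way, so a trace as the only source of the shared ranking was not ruled out. Runs of G enter both the median of 0.058 and the rho of -0.484. The 19 of these 8-mers with at least 5 G in a row had median signals of 1.12 on the ETS1 array and 13.5 on the EGR1 array. The 19 without had 1.04 and 22.7, so the size of any trace cannot be told.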
